A study of Mus musculus with 28 samples.

How the data were processed

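The series holds 28 messenger RNA libraries of mouse bone marrow-derived macrophages in 2 experiments. Per the labels, the mutant mice were backcrossed to C57BL/6, male and female animals were used, marrow cells were grown for 6 days with L929 cell-conditioned medium, and the cells were then kept for 24 h without it. Per the labels' protocols, libraries were made with the Kapa mRNA HyperPrep kit. The first experiment was sequenced for 100 cycles and holds 12 libraries (WT, Irgm1-KO and Irgm_IFNAR-KO, n = 4 each), and the second was sequenced for 50 cycles and holds 16 (WT and Irgm1KO, each with a control and a 50 µM fenofibrate group, n = 4 each). The labels used here give neither the duration of the fenofibrate exposure nor the treatment of control cells. Samples were grouped by their titles, and each column of the tables was matched to its sample by name.

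The deposited values are whole-number read counts per Ensembl gene, not normalized, in 1 table per experiment. Per the submitters' processing notes, fastp, STAR and DESeq2 were used with mouse build GRCm39, and versions and roles are not given. The counting tool, the annotation release and the use of strand are not given in the sources used here, so genes with near-identical copies (such as Hspa1a and Hspa1b, the Apol9 pair and H2-Q genes), overlapping genes and antisense genes are uncertain. The first table holds 15423 genes, each with at least 10 counts in some library, so it had been filtered before deposit, and the second holds 56941, of which 26301 are zero throughout. Neither table holds values without a gene ID. Symbols were found for 99.6% and 91.2% of the IDs, and 841 of 844 entries of the gene lists were matched, 5 of them by synonym. Gene names came from tables that pair Ensembl IDs with symbols. Transcript lengths and gene positions came from a GENCODE annotation of the earlier build. The positions served only for distances to Irgm1 and Ifnar1, and no coordinates are printed.

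Library totals ran from 48.7 to 70.5 M counts in the first experiment, with group means of 55.8 ± 10.0 (WT), 56.8 ± 4.7 (Irgm1-KO) and 56.4 ± 3.9 M (Irgm_IFNAR-KO; SD, n = 4). In the second they ran from 82.4 to 120.8 M, with group means of 101.5 ± 13.0 (WT control), 100.7 ± 14.3 (WT fenofibrate), 99.1 ± 16.4 (Irgm1KO control) and 89.8 ± 6.0 M (Irgm1KO fenofibrate). A single gene without a symbol, ENSMUSG00000119584, took 1.59% to 11.37% of counts in the first experiment and 1.26% to 10.29% in the second. All pairs of libraries within a group differed by far more than counting noise, so each was counted as its own library.

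Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13998 and 15429 genes, libraries were scaled by TMM, and all groups of an experiment entered 1 quasi-likelihood fit with robust dispersion estimates (biological coefficient of variation 0.172 and 0.12). Each comparison was a contrast tested with glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Values per gene are counts per M of the scaled library size, as mean ± SD over 4 libraries. A fitted fold is not given for a gene with a group at 0 to 3 counts.

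Before the data were examined, 23 gene lists and 14 lists of cell type markers were fixed, as were the comparisons, the alternatives and the rule for named genes. Lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the gene lists and over the marker lists separately, and again with an estimated correlation and with fry, whose p asks whether a list's genes move one way on balance. Counts of members that changed are given with adjustment over all genes and with adjustment over the list alone. Lists share members, so their calls are not independent. Ifih1, Dhx58 and Zbp1 are in the nucleic acid sensing and interferon-stimulated lists. Ccl5 and Nos2 are in the cytokine and interferon-gamma-type lists. The text names Irgm1 and Ifnar1; the 6 largest rises and 6 largest falls per comparison among called genes with at least 5 CPM in the higher group and no overlap between groups (for the interaction, called genes with at least 5 CPM in the highest group), leaving out predicted genes, Xist and Y-linked genes; up to 4 members of each list with the smallest p; and 22 genes fixed by name, of which Ppara and Pdk4 were not among the tested genes. Some genes that this rule covers are not reported here.

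The replicate numbers of the titles were checked for pairing. In the second experiment, deviations from the group mean of same-numbered control and fenofibrate libraries correlated with r from 0.38 to 0.49 in WT and from 0.26 to 0.37 in Irgm1KO, above every other pairing, so these numbers pair the libraries, and a fit with a block for each number within a genotype was added. The pairing comes from the data, not from the labels.

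Alternatives were RLE scaling, no low-count filter, a filter of 5 CPM, DESeq2 1.42.0, a fit of the compared groups alone, the replicate number as a block, log2 Xist as a covariate, and leaving out each library in turn. Added after the data were seen were the block within genotype, leaving out ENSMUSG00000119584, and leaving out the 3 libraries of the first experiment farthest out within their groups. Overlaps between comparisons that share libraries were set against 20 simulations of unchanged groups and against splits of the shared libraries. For the comparisons that share WT this was added after the data were seen, with 20 further simulations where only Irgm1-KO changed.

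The fits were tested on simulated counts with 200 genes changed by known amounts. Of genes changed 2-fold, 88.1% were recovered in each comparison of the first experiment and 97%, 95.5%, 97% and 91% in the Irgm1KO, WT fenofibrate, Irgm1KO fenofibrate and interaction comparisons of the second. Of genes changed 1.5-fold, 37.3% to 41.8% were recovered in the first experiment and 67.2% to 86.6% in the second. Between 2.6% and 8.6% of calls were false, in a single simulation per comparison. Genes were drawn independently and far fewer were changed than were called in the data, so these shares need not hold for the real calls. Correlations over libraries were tested with 100000 permutations, two-sided. Further tools were Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.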

Results

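Messenger RNA was sequenced from primary bone marrow-derived macrophages (BMM), cells grown from mouse bone marrow, in 2 experiments. The first compared wild-type cells (WT), cells lacking Irgm1 (Irgm1-KO) and cells lacking both Irgm1 and the type I interferon receptor IFNAR (Irgm_IFNAR-KO), with 4 libraries in each of 3 groups. Irgm1 is an immunity-related GTPase that interferons induce. The second experiment exposed WT and Irgm1KO cells to a control condition or to 50 µM fenofibrate, a lipid-lowering drug that activates the nuclear receptor PPAR alpha, with 4 libraries in each of 4 groups. Total counts per library ran from 48.7 to 70.5 M (M, mega) in the first experiment and from 82.4 to 120.8 M in the second. Genes are called higher or lower at an adjusted p below 0.05 in edgeR's quasi-likelihood test, and gene lists fixed before the data were examined were tested with camera. Same-numbered libraries of a genotype in the second experiment had matching Xist and Y-linked expression and deviated together. The labels do not state that replicates were separate animals, so p-values measure the spread between these libraries.

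The targeted gene was measured first in every library. In the first experiment Irgm1 (ENSMUSG00000046879) lay between 1190 and 1350 counts per M counts of the library (CPM) in WT, between 628 and 839 in Irgm1-KO and between 641 and 786 in Irgm_IFNAR-KO libraries. In the second it lay between 1510 and 1670 CPM in WT control, 1470 and 1670 in WT fenofibrate, 991 and 1040 in Irgm1KO control and 1020 and 1140 in Irgm1KO fenofibrate libraries. Irgm1 thus fell in knockout cells in both experiments, with a log2 fold change of -0.77 (SE 0.102, adjusted p = 8.32e-05) in the first and -0.65 (SE 0.0542, adjusted p = 5.3e-08) in the second. Gene-level counts can include parts of a gene outside a deletion, so the remaining counts do not show that an intact transcript was made. Ifnar1 (ENSMUSG00000022967) was at 136.1 ± 5.54 CPM (SD, n = 4) in WT and 96 ± 28.8 in Irgm_IFNAR-KO, where the individual libraries read 114, 109, 53.1 and 108. This difference was not called (log2 fold change -0.50, SE 0.188, adjusted p = 0.12). Every Irgm_IFNAR-KO library lay below the WT libraries (128 to 141 CPM), while the highest, at 114, lay above the lowest Irgm1-KO library, at 112.

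The comparison of Irgm1-KO with WT asked how loss of Irgm1 changes macrophages. Irgm1-KO cells expressed a broad type I interferon program. Of 56 measured type I interferon-stimulated genes, 52 rose and 0 fell (53 and 0 adjusted over the list alone), with a median log2 fold change of 1.49 (camera adjusted p = 1.07e-39). Oasl1 (ENSMUSG00000041827), which inhibits translation of Irf7, rose from 35.7 ± 2.45 to 713 ± 60.3 CPM (SD, n = 4, log2 fold change 4.32, SE 0.112, adjusted p = 5.7e-10). The antiviral GTPase gene Mx1 rose from 55.1 ± 5.71 to 671 ± 45.7 CPM (log2 fold change 3.61, SE 0.121). Ifit1, an antiviral RNA-binding protein, rose from 212 ± 13 to 948 ± 96.2 CPM. Irf7, a transcription factor of interferon genes, rose from 462 ± 108 to 2457 ± 362.5 CPM. Isg15, a ubiquitin-like modifier, rose from 136 ± 34.8 to 1058 ± 349 CPM, with 1 Irgm1-KO library at 1580. The Ifnb1 transcript (ENSMUSG00000048806), which encodes interferon beta, was scarce in WT at 0.123 ± 0.0637 CPM and reached 2.11 ± 1.13 CPM in Irgm1-KO (log2 fold change 4.12, SE 0.52, adjusted p = 5.3e-05).

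Inflammatory transcripts rose with the interferon program. Among 28 measured inflammatory cytokines and chemokines, 21 rose and 2 fell (22 and 2 adjusted over the list alone, camera adjusted p = 3.28e-12). The monocyte chemoattractant Ccl2 rose from 20.1 ± 1.84 to 107 ± 4.83 CPM (log2 fold change 2.41, SE 0.0987), Ccl5 from 94.5 ± 4.35 to 885 ± 84.1 CPM. The interleukin-1 receptor antagonist gene Il1rn rose by 2.98 on the log2 scale (SE 0.115, adjusted p = 8.1e-09), while Il1b fell from 2.50 ± 0.669 to 0.951 ± 0.104 CPM. The tumor necrosis factor gene Tnf rose by 1.08 (SE 0.133, adjusted p = 4.4e-05). NF-kB feedback and target genes rose in 18 of 24 cases with 0 falls (18 and 0 adjusted over the list alone, camera adjusted p = 1.99e-08, and adjusted p = 0.0891 with an estimated correlation), among them the signalling adaptor Traf1 (log2 fold change 2.12, SE 0.0966). Of 21 genes of MHC class I presentation 13 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 8.35e-07, and adjusted p = 0.095 with an estimated correlation). H2-K1 rose by 0.67 (SE 0.0717). Of 22 nucleic acid sensing genes 12 rose and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000219, and adjusted p = 0.095 with an estimated correlation). Among them the RNA sensor Ifih1, which is also in the interferon-stimulated list, was at 1.75 on the log2 scale (SE 0.103). In the interferon-gamma-type list, 14 of 30 rose and 3 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00265, and adjusted p = 0.135 with an estimated correlation), led by Ccl5 and by the nitric oxide synthase gene Nos2 (log2 fold change 4.08, SE 0.306).

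Cholesterol biosynthesis genes and mitochondrially encoded transcripts moved the other way, calls that held with an estimated correlation (adjusted p = 0.0331 and 0.0247). Cholesterol biosynthesis genes fell in 17 of 25 cases and rose in 1 (19 and 1 adjusted over the list alone), with a median log2 fold change of -0.67 (camera adjusted p = 8.86e-08). Squalene epoxidase, Sqle, fell from 8.11 ± 1.29 to 2.71 ± 0.189 CPM (SD, n = 4). All 9 measured mitochondrially encoded transcripts fell (9 of 9 adjusted over the list alone, median -1.45, camera adjusted p = 2.16e-12). The mt-Cytb transcript went from 1144 ± 56.5 to 275 ± 34.7 CPM, and their share of all counts was 0.60% ± 0.04 in Irgm1-KO against 1.48% ± 0.07 in WT. Of 42 nuclear-encoded oxidative phosphorylation genes 2 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.949). Fatty acid synthesis and desaturation genes fell in 15 of 23 cases and rose in 3 (15 and 3 adjusted over the list alone, camera adjusted p = 0.0116, and adjusted p = 0.279 with an estimated correlation). Peroxisomal enzymes fell in 15 of 37 cases and rose in 3 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00367, and adjusted p = 0.382 with an estimated correlation). Hsd17b4, the multifunctional enzyme of peroxisomal beta-oxidation, went from 119 ± 3.91 to 64.7 ± 2.98 CPM (log2 fold change -0.88, SE 0.0618). The catalase gene Cat (log2 fold change 0.03) was not called. The peroxisome biogenesis list was not called either (5 of 25 rose and 2 fell, 5 and 2 adjusted over the list alone, camera adjusted p = 0.547). Nor were mitochondrial fatty acid oxidation genes (2 of 24 rose and 6 fell, 2 and 5 adjusted over the list alone, camera adjusted p = 0.415) or PPAR target genes (5 of 28 rose and 9 fell, 5 and 10 adjusted over the list alone, 0.865). LXR target genes were not called as a list (2 of 17 rose and 5 fell, 2 and 5 adjusted over the list alone, camera adjusted p = 0.268, but 0.00263 with fry).

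Stress and cell-cycle genes also changed, but calls of the ATF4, NRF2 and proliferation lists were lost with an estimated correlation (adjusted p = 0.095, 0.095 and 0.123). The list of ATF4 and unfolded protein response genes held 18 rises and 10 falls among 34 (18 and 11 adjusted over the list alone, camera adjusted p = 8.35e-07, and adjusted p = 0.095 with an estimated correlation). Trib3 rose by 3.96 (SE 0.156), while the asparagine synthetase gene Asns went from 9.75 ± 0.863 to 81.3 ± 3.76 CPM. NRF2 and oxidative stress genes rose in 17 of 28 cases (17 rises and 1 fall adjusted over the list alone, camera adjusted p = 1.09e-05, and adjusted p = 0.095 with an estimated correlation). Among them heme oxygenase 1, Hmox1, was at 1.13 on the log2 scale (SE 0.08). Proliferation genes fell in 28 of 40 cases and rose in 4 (28 and 4 adjusted over the list alone, median -1.36, camera adjusted p = 5.24e-12, and adjusted p = 0.123 with an estimated correlation). The spindle midzone gene Prc1 fell by 2.07 (SE 0.124) while cyclin E1, Ccne1, rose by 1.67 (SE 0.101). Alternative activation markers fell in 14 of 21 cases and rose in 4 (14 and 4 adjusted over the list alone, camera adjusted p = 0.00287). The interleukin-4 receptor gene Il4ra was at -1.22 on the log2 scale (SE 0.0773) and the apoptotic-cell receptor gene Timd4 at 5.66 (SE 0.311). The heat-shock genes Hspa1b and Hspa1a, which are near-identical copies whose reads may not be told apart, rose from 0.573 ± 0.131 to 41.2 ± 10.8 CPM and from 0.603 ± 0.072 to 29.5 ± 7.19 CPM. Hpgd, which degrades prostaglandins, showed the largest fall among genes of at least 5 CPM, from 17.2 ± 3.56 to 0.175 ± 0.0718 CPM (log2 fold change -6.59, SE 0.255). Macrophage markers as a list were not called (1 of 10 rose and 3 fell, 1 and 3 adjusted over the list alone, camera adjusted p = 0.346). Neutrophil markers fell in 5 of 7 cases (5 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.516 with an estimated correlation). The neutrophil call ended with log2 Xist as a covariate (0.153) or without the 3 libraries farthest out within their groups (0.15).

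Across 13998 tested genes, 2767 rose and 2893 fell in Irgm1-KO, of which 837 rose and 1007 fell over 2-fold. With Xist as a covariate the number that rose was 4252. Libraries within each group of this experiment spread along 1 axis that held 53.8% of the within-group variance and followed Xist.

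The comparison of Irgm_IFNAR-KO with Irgm1-KO asked which of these changes are absent when the type I interferon receptor is missing too. No group lacked the receptor alone. Irgm1 effects that need the receptor therefore cannot be told apart from effects of receptor loss itself. Without the receptor, the interferon program of Irgm1-deficient cells was lost, inflammatory transcripts fell, and cholesterol biosynthesis and mitochondrially encoded transcripts returned. Of 56 interferon-stimulated genes 54 fell and 0 rose (55 and 0 adjusted over the list alone, median -2.72, camera adjusted p = 2.36e-73). Oasl1 went from 713 ± 60.3 to 2.65 ± 0.329 CPM (SD, n = 4, log2 fold change -8.07, SE 0.134, adjusted p = 3.2e-12), Ifit1 from 948 ± 96.2 to 74.2 ± 1.83 and Irf7 from 2457 ± 362.5 to 28.7 ± 3.02 CPM. Inflammatory cytokines and chemokines fell in 21 of 28 cases and rose in 3 (21 and 3 adjusted over the list alone, camera adjusted p = 5.53e-13). Ccl2 fell to 5.16 ± 0.644 CPM (log2 fold change -4.37, SE 0.109), Cxcl10 by 1.20 (SE 0.0981) and Tnf by 0.47 (SE 0.131), while Il1b rose from 0.951 ± 0.104 to 4.88 ± 0.58 CPM. Nucleic acid sensing genes fell in 14 of 22 cases and rose in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 2.89e-07). MHC class I genes fell in 16 of 21 cases (18 adjusted over the list alone, camera adjusted p = 2.36e-09, and adjusted p = 0.0545 with an estimated correlation). MHC class II genes rose in 7 of 12 cases (7 adjusted over the list alone, camera adjusted p = 0.00172, and adjusted p = 0.404 with an estimated correlation). The invariant chain Cd74 went from 4524 ± 64.8 to 7927 ± 597 CPM.

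Cholesterol biosynthesis genes rose in 19 of 25 cases and fell in 1 (19 and 1 adjusted over the list alone, camera adjusted p = 3.38e-10), with Sqle at 13.2 ± 1.3 CPM in Irgm_IFNAR-KO (log2 fold change 2.28, SE 0.126). Mitochondrially encoded transcripts rose in 8 of 9 cases (8 of 9 adjusted over the list alone, median 1.86, camera adjusted p = 3.05e-12). Their share of counts was 1.63% ± 0.07. Alternative activation markers rose in 12 of 21 cases and fell in 5 (12 and 6 adjusted over the list alone, camera adjusted p = 0.00251). Among them the lectin gene Mgl2 was at 4.02 on the log2 scale (SE 0.237). Peroxisomal enzymes rose in 16 of 37 cases and fell in 2 (16 and 3 adjusted over the list alone, camera adjusted p = 0.00567, and adjusted p = 0.433 with an estimated correlation). Hsd17b4 returned to 121 ± 2.75 CPM. ATF4 and unfolded protein response genes fell in 18 of 34 cases and rose in 5 (18 and 5 adjusted over the list alone, camera adjusted p = 2.02e-06, and adjusted p = 0.142 with an estimated correlation). Ddit3 was at -3.01 on the log2 scale (SE 0.0984). NF-kB genes, with 4 rises and 9 falls among 24 (5 and 9 adjusted over the list alone), and proliferation genes, with 15 rises and 14 falls among 40 (18 and 14 adjusted over the list alone), were not called as lists (camera adjusted p = 0.295 and 0.86). In all, 3014 genes rose and 2984 fell. With Xist as a covariate the number that rose was 4640.

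**Figure D1:**
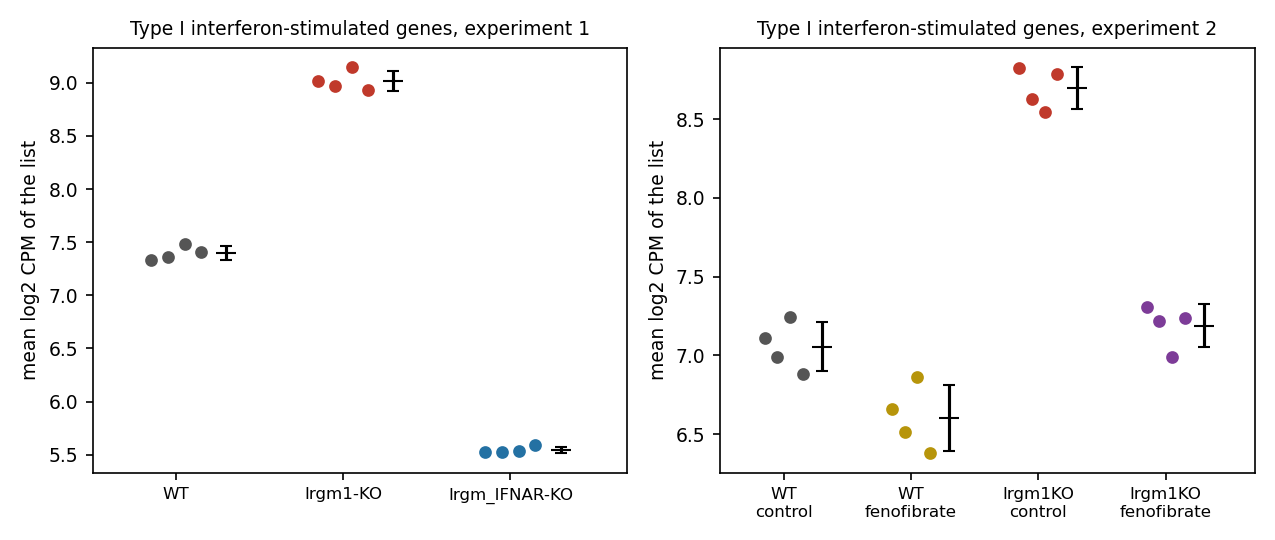
Mean log2 CPM of the type I interferon-stimulated gene list in each library (y axis, log2 scale) by group (x axis), for both experiments. Points are libraries, and bars show the mean ± SD over 4 libraries. In the first experiment WT libraries lie between 7.33 and 7.48, Irgm1-KO between 8.93 and 9.15 and Irgm_IFNAR-KO between 5.52 and 5.59. In the second, Irgm1KO control libraries lie between 8.54 and 8.83 and Irgm1KO fenofibrate libraries between 6.99 and 7.31.

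The comparison of Irgm_IFNAR-KO with WT showed what remained changed when Irgm1 and the receptor were both missing. Interferon-stimulated genes lay below WT, cell-cycle genes were low, and NF-kB target genes were raised. Of 56 interferon-stimulated genes 51 fell and 0 rose (52 and 0 adjusted over the list alone, median -1.30, camera adjusted p = 7.16e-109), with Irf7 at 28.7 ± 3.02 CPM against 462 ± 108 in WT (SD, n = 4, log2 fold change -4.01, SE 0.177, adjusted p = 4.9e-08). Proliferation genes fell in 35 of 40 cases and rose in 0 (37 and 0 adjusted over the list alone, median -1.26, camera adjusted p = 5.51e-49). The kinesin gene Kif23 went from 28.5 ± 2.95 to 9.81 ± 1.46 CPM. NF-kB genes rose in 15 of 24 cases and fell in 0 (17 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 5.13e-15). Among them the mitochondrial superoxide dismutase gene Sod2 was at 0.96 on the log2 scale (SE 0.0899) and Ier3 at 0.85 (SE 0.0739). Tnf rose by 0.60 (SE 0.132, adjusted p = 0.0095) and Il1b by 0.97 (SE 0.169). Ccl2 fell by 1.96 (SE 0.0995), and Cxcl10 was at 463 ± 32 CPM against 467 ± 43. Over the whole list of inflammatory cytokines and chemokines, 5 of 28 rose and 11 fell (5 and 14 adjusted over the list alone, camera adjusted p = 0.00206, and adjusted p = 0.241 with an estimated correlation).

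Glycolysis and hypoxia genes rose in 12 of 34 cases and fell in 1 (18 and 2 adjusted over the list alone, camera adjusted p = 3.36e-07, and adjusted p = 0.0713 with an estimated correlation). The glucose transporter gene Slc2a1 was at 0.50 on the log2 scale (SE 0.0794). Cholesterol biosynthesis genes rose in 6 of 25 cases (7 adjusted over the list alone, camera adjusted p = 0.000854, and adjusted p = 0.186 with an estimated correlation). Lysosomal genes fell in 10 of 46 cases (12 adjusted over the list alone, camera adjusted p = 0.0125, and adjusted p = 0.241 with an estimated correlation). Peroxisomal enzymes held 1 rise and 0 falls among 37 (0 and 0 adjusted over the list alone) and mitochondrially encoded transcripts 3 rises among 9 (5 adjusted over the list alone). Neither list was called (camera adjusted p = 0.691 and 0.099). Some transcripts stayed far above WT. Timd4 was at 8.86 ± 1.07 against 0.277 ± 0.11 CPM (log2 fold change 4.95, SE 0.309), Hspa1b was at 11.4 ± 1.35 CPM (4.28, SE 0.224) and the acute-phase gene Saa3 was at 137 ± 70.7 against 8.64 ± 1.03 CPM (3.99, SE 0.398). In total 552 genes rose and 1150 fell. The rises numbered 2126 and the falls 2132 with Xist as a covariate. The rises numbered 337 without Irgm_IFNAR-KO replicate 3, 360 without replicate 2, 361 without replicate 1 and 367 without WT replicate 3.

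Counted gene by gene, 4503 of the 5660 genes changed in Irgm1-KO against WT (79.6%) changed in the opposite direction in Irgm_IFNAR-KO against Irgm1-KO. Of 2767 genes that had risen 2232 fell and 7 rose again, and of 2893 that had fallen 2271 rose and 44 fell again. Independent lists would share 590 and 623. Measured against WT, 216 of the risen genes stayed above, 446 of the fallen stayed below, 425 risen genes ended below WT and 164 fallen genes ended above it. Independent lists would give 109, 238, 227 and 114. Both comparisons with WT use the WT libraries, so some agreement arises without any effect. Over all genes their fold changes correlated with r -0.03, against 0.51 for simulated unchanged groups and 0.14 where only Irgm1-KO was simulated as changed. The covariance was -0.0124, against 0.027 and 0.0293. The unchanged groups called 0.1 genes per comparison on average, so their 0 shared calls were fixed in advance. With only Irgm1-KO changed, Irgm_IFNAR-KO against WT called 0 genes, so shared calls were fixed at 0 there too. With the WT libraries split 2 and 2 between the comparisons, 380 to 506 genes changed the same way, against 662 unsplit, and 351 to 560 changed opposite ways, against 589. Split comparisons hold fewer libraries and call fewer genes. They kept 111 to 158 genes above WT and 269 to 348 below, against 34 to 83 and 113 to 180 for independent lists. Risen genes ending below WT numbered 289 to 387 and fallen genes ending above it 62 to 173, against 105 to 170 and 36 to 88. The comparisons that measure reversal both use the Irgm1-KO libraries, so some reversal arises without any effect. Unchanged groups simulated against the same libraries gave a correlation of fold changes across genes of -0.50 against -0.85 observed. Their covariance was -0.0264 against -0.749. They reversed 0 genes, an outcome fixed in advance because unchanged groups give almost no calls. The simulations drew each gene independently, without the axis along which libraries of a group spread. With the Irgm1-KO libraries split 2 and 2 between the comparisons, 3150 to 3333 genes reversed and the correlation lay between -0.79 and -0.73. Fewer genes could reverse in these splits, since 2143 to 2519 had risen and 2134 to 2503 had fallen against WT, compared with 2767 and 2893 unsplit. Without a group lacking the receptor alone, the reversed genes may include effects of receptor loss itself.

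The second experiment compared Irgm1KO with WT again under control conditions, at greater depth. The Y-linked gene Eif2s3y was expressed in WT control replicates 2 and 4 (33.4 and 28.5 CPM) and in Irgm1KO control replicate 3 (36.3 CPM). Sex was thus spread unevenly between the genotypes and was not a term of the main fit. Differences between genotypes in this experiment, the interaction included, may hold a part due to sex. The interferon program recurred, with 53 of 56 interferon-stimulated genes raised and 0 lowered (53 and 1 adjusted over the list alone, median 1.38, camera adjusted p = 4.01e-54, and adjusted p = 0.0613 with an estimated correlation). Oasl1 rose from 32.7 ± 3.42 to 628 ± 76.3 CPM (SD, n = 4, log2 fold change 4.26, SE 0.142, adjusted p = 9.2e-12), Isg15 from 52.6 ± 9.24 to 453 ± 76.9 and Irf7 from 259 ± 57.2 to 1559 ± 176 CPM. MHC class I genes rose in 18 of 21 cases (18 adjusted over the list alone, camera adjusted p = 1.09e-11, and adjusted p = 0.201 with an estimated correlation). Inflammatory cytokines and chemokines rose in 21 of 33 cases and fell in 1 (21 and 2 adjusted over the list alone, camera adjusted p = 1.12e-06, and adjusted p = 0.201 with an estimated correlation). Ccl2 was at 2.79 on the log2 scale (SE 0.167), Tnf at 0.56 (SE 0.0837) and Il1b at -1.36 (SE 0.291). NF-kB genes, with 10 rises and 5 falls among 24 (10 and 5 adjusted over the list alone), were not called as a list here (camera adjusted p = 0.334). Il6 stayed at or below 0.162 ± 0.043 CPM in every group of this experiment.

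Mitochondrially encoded transcripts fell in 8 of 9 cases (8 of 9 adjusted over the list alone, median -1.16, camera adjusted p = 1.69e-10, and adjusted p = 0.0613 with an estimated correlation). The mt-Cytb transcript went from 1972 ± 159 to 639 ± 127 CPM. Nuclear-encoded oxidative phosphorylation genes rose in 23 of 41 cases and fell in 4 (23 and 4 adjusted over the list alone, camera adjusted p = 0.00287, and adjusted p = 0.615 with an estimated correlation). The cytochrome c gene Cycs went from 62.3 ± 3.88 to 135 ± 9.01 CPM (log2 fold change 1.11, SE 0.0593). Cholesterol biosynthesis genes fell in 19 of 25 cases (20 adjusted over the list alone, camera adjusted p = 4.03e-06, and adjusted p = 0.267 with an estimated correlation). Peroxisomal enzymes fell in 22 of 39 cases and rose in 6 (23 and 6 adjusted over the list alone, camera adjusted p = 0.00514, and adjusted p = 0.0613 with an estimated correlation). The isocitrate dehydrogenase gene Idh1 went from 109 ± 3.47 to 54.7 ± 4.24 CPM. Fatty acid synthesis and desaturation genes fell in 13 of 23 cases and rose in 4 (13 and 5 adjusted over the list alone, camera adjusted p = 0.0183, and adjusted p = 0.267 with an estimated correlation). Fatty acid synthase, Fasn, was at -0.93 on the log2 scale (SE 0.0843). Proliferation genes were split, with 16 rises and 22 falls among 40 (16 and 22 adjusted over the list alone, camera adjusted p = 0.67). The replication genes Mcm6 (1.09, SE 0.064) and Pcna (0.90, SE 0.0494) rose. Alternative activation markers, lower in the first experiment, were not called here (6 of 20 rose and 7 fell, camera adjusted p = 0.419). NRF2 and oxidative stress genes were not called either (13 of 29 rose and 2 fell, camera adjusted p = 0.0637). Adjustment over the list alone gave the same counts for both. With fry both lists were called (adjusted p = 0.00925 and 0.00646). The heat-shock genes Hspa1b and Hspa1a again rose, to 62.4 ± 8.16 and 41.9 ± 3.06 CPM.

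Without a block, camera called no list of cell type markers in this comparison, although single markers changed. Macrophage markers fell in 6 of 10 cases and rose in 1 (6 and 1 adjusted over the list alone, median log2 fold change -0.44, camera adjusted p = 0.0571, and 0.037 with the replicate number as a block). Osteoclast markers rose in 3 of 5 cases (3 adjusted over the list alone, median 1.82, camera adjusted p = 0.0571, and 0.0466 with the block). Neutrophil markers fell in 3 of 4 cases (3 adjusted over the list alone, median -2.87, camera adjusted p = 0.131, and 0.029 with the block). Fibroblast markers fell in 4 of 5 cases and rose in 1 (4 and 1 adjusted over the list alone, median -3.82, camera adjusted p = 0.131, and 0.037 with the block). Same-numbered libraries of the WT and Irgm1KO control groups did not deviate together (r from -0.26 to -0.02), so the data give this block no basis here. Without WT control replicate 1, macrophage (0.0303), osteoclast (0.0328) and neutrophil (0.0328) markers were called. Macrophage and osteoclast markers were also called without WT control replicate 4 (0.0453 for both), Irgm1KO control replicate 1 (0.0363 for both) or Irgm1KO control replicate 4 (0.0292 for both). Macrophage markers were called with Xist as a covariate too (0.0473). With fry every marker list except that of T cells was called (adjusted p of at most 0.00349), and with an estimated correlation none was (adjusted p of at least 0.456).

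Altogether 4219 genes rose and 4026 fell among 15429 tested. Over the 13676 genes tested in both experiments, the Irgm1-deficiency effects correlated across genes with Pearson's r 0.83 and Spearman's rho 0.76, genes not being independent replicates. Of 4348 genes called in both, 4296 (98.8%) went the same way, 2148 up and 2148 down. Independent lists would share 793 and 794, and 52 genes went opposite ways.

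**Figure D2:**
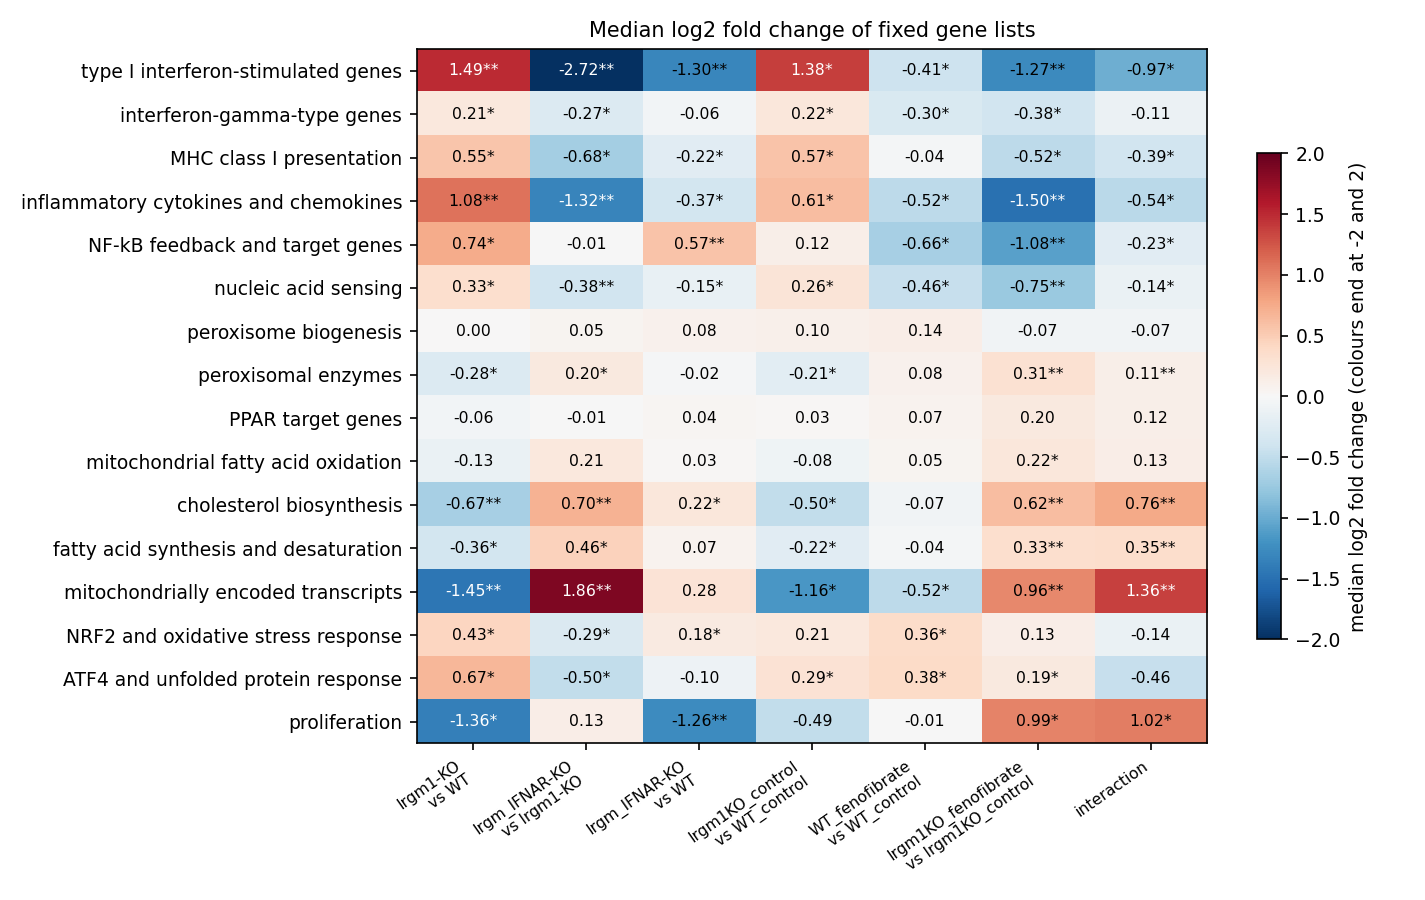
Median log2 fold change (colour, from -2 to 2) of 16 gene lists (y axis) in the 7 comparisons (x axis), with 1 asterisk where camera called the list and 2 where the call held with an estimated correlation. Type I interferon-stimulated genes have medians of 1.49 and 1.38 in the Irgm1-deficiency comparisons, -2.72 in Irgm_IFNAR-KO against Irgm1-KO and -1.27 with fenofibrate in Irgm1KO cells.

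Fenofibrate in WT macrophages lowered NF-kB, inflammatory and pathogen-sensing genes, calls that were lost with an estimated correlation (adjusted p = 0.0964, 0.112 and 0.112). Interferon-stimulated genes had a median change of -0.41 on the log2 scale. NF-kB genes fell in 21 of 24 cases and rose in 0 (22 and 0 adjusted over the list alone, median -0.66, camera adjusted p = 5.29e-20, and adjusted p = 0.0964 with an estimated correlation). Inflammatory cytokines and chemokines fell in 17 of 33 cases and rose in 1 (19 and 2 adjusted over the list alone, camera adjusted p = 2.85e-08, and adjusted p = 0.112 with an estimated correlation). Tnf (ENSMUSG00000024401) went from 41.7 ± 3.08 to 19.4 ± 1.54 CPM (SD, n = 4, log2 fold change -1.10, SE 0.0851, adjusted p = 3.5e-07), with 1 treated library at 17.1. Il1b went from 3.26 ± 0.364 to 0.237 ± 0.138 CPM and Cxcl10 from 885 ± 52.5 to 233 ± 70.8 CPM. Nucleic acid and pathogen sensing genes fell in 18 of 22 cases and rose in 0 (19 and 0 adjusted over the list alone, camera adjusted p = 5.48e-13, and adjusted p = 0.112 with an estimated correlation). Among them Tmem173, which encodes STING, was at -0.84 on the log2 scale (SE 0.0572) and Tlr2 at -1.25 (SE 0.0921). Interferon-stimulated genes fell in 42 of 56 cases and rose in 2 (43 and 2 adjusted over the list alone, camera adjusted p = 7.85e-13, and adjusted p = 0.342 with an estimated correlation). Ifit1 went from 181 ± 24.1 to 118 ± 25.8 CPM. Irf7 was at 259 ± 57.2 and 225 ± 51 CPM, a difference that was not called (adjusted p = 0.39), but was with same-numbered libraries of a genotype taken as a block (0.0442). MHC class II genes fell in 8 of 12 cases (9 adjusted over the list alone, camera adjusted p = 4.28e-07, and adjusted p = 0.19 with an estimated correlation). Cd74 went from 4840 ± 645 to 2521 ± 435 CPM.

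Among lipid genes, PPAR target genes were not called as a list in WT cells (11 of 28 rose and 7 fell, 11 and 7 adjusted over the list alone, camera adjusted p = 0.566). The fatty acid-binding protein gene Fabp5 rose from 244.6 ± 19.7 to 506.6 ± 108 CPM (log2 fold change 1.05, SE 0.124) and the peroxisome proliferation gene Pex11a from 5.09 ± 0.108 to 8.23 ± 0.61 CPM (0.69, SE 0.0955). Peroxisomal enzymes went both ways, with 10 rises and 10 falls among 39 (11 and 10 adjusted over the list alone, camera adjusted p = 0.647). The ubiquitin ligase gene Trim37 rose by 0.61 (SE 0.0662) and the membrane protein gene Pxmp2 fell by 1.06 (SE 0.205). Cholesterol biosynthesis genes were not called as a list (1 of 25 rose and 7 fell, 1 and 7 adjusted over the list alone, camera adjusted p = 0.159, but 0.0155 without WT control replicate 3 and 0.0419 without WT fenofibrate replicate 1). LXR target genes fell in 8 of 17 cases and rose in 4 (8 and 4 adjusted over the list alone, camera adjusted p = 0.00483, and adjusted p = 0.112 with an estimated correlation). The cholesterol exporter gene Abca1 went from 198.1 ± 25.4 to 38.4 ± 12.5 CPM. Mitochondrially encoded transcripts fell in 7 of 9 cases (7 of 9 adjusted over the list alone, median -0.52, camera adjusted p = 2.78e-06, and adjusted p = 0.125 with an estimated correlation). ATF4 and unfolded protein response genes rose in 17 of 33 cases and fell in 12 (18 and 12 adjusted over the list alone, camera adjusted p = 0.000304, and adjusted p = 0.217 with an estimated correlation). The pseudokinase gene Trib3 went from 4.0 ± 1.23 to 48.6 ± 23.9 CPM. Glycolysis and hypoxia genes rose in 18 of 33 cases and fell in 4 (19 and 4 adjusted over the list alone, camera adjusted p = 0.000637, and adjusted p = 0.342 with an estimated correlation). Macrophage markers fell in 6 of 10 cases and rose in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 2.68e-07). The growth factor receptor gene Csf1r went from 3203 ± 140.5 to 2008 ± 150.5 CPM, and monocyte and progenitor markers fell in 6 of 7 cases (6 adjusted over the list alone, camera adjusted p = 0.000478). The chemokine receptor gene Ccr2 was at -2.49 on the log2 scale (SE 0.393). In total 2794 genes rose and 2613 fell.

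Fenofibrate in Irgm1KO macrophages lowered nearly the whole interferon program and raised lipid-synthesis genes, peroxisomal enzymes and mitochondrially encoded transcripts. Of 56 interferon-stimulated genes 55 fell and 0 rose (55 and 0 adjusted over the list alone, median -1.27, camera adjusted p = 3.95e-70). Isg15 went from 453 ± 76.9 to 84.3 ± 13.5 CPM (SD, n = 4, log2 fold change -2.43, SE 0.177, adjusted p = 5.4e-08), Oasl1 from 628 ± 76.3 to 121 ± 18.8 CPM and Ifnb1 from 1.55 ± 0.51 to 0.139 ± 0.0676 CPM. Inflammatory cytokines and chemokines fell in 26 of 33 cases and rose in 1 (26 and 1 adjusted over the list alone, median -1.50, camera adjusted p = 1.09e-15). Cxcl10 went from 1227 ± 145 to 176 ± 21.3 CPM and Tnf from 61.6 ± 1.66 to 25.6 ± 3.69 CPM. NF-kB genes fell in 23 of 24 cases (23 adjusted over the list alone, camera adjusted p = 2.85e-22). Nucleic acid sensing genes fell in 20 of 22 (20 adjusted over the list alone, camera adjusted p = 2e-15). MHC class I genes fell in 17 of 21 (18 adjusted over the list alone, camera adjusted p = 4.55e-11, and adjusted p = 0.0964 with an estimated correlation). In the interferon-gamma-type list 20 of 30 fell and 2 rose (20 and 2 adjusted over the list alone, camera adjusted p = 6.06e-08, and adjusted p = 0.0911 with an estimated correlation).

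Cholesterol biosynthesis genes rose in 24 of 25 cases and fell in 1 (24 and 1 adjusted over the list alone, median 0.62, camera adjusted p = 4.08e-13). Sqle rose by 1.77 on the log2 scale (SE 0.131). Fatty acid synthesis and desaturation genes rose in 13 of 23 cases and fell in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 6.78e-06). Fasn went from 32.7 ± 0.965 to 59.4 ± 7.38 CPM. Peroxisomal enzymes rose in 21 of 39 cases and fell in 5 (22 and 5 adjusted over the list alone, median 0.31, camera adjusted p = 0.000281). Among them Idh1 rose by 0.72 on the log2 scale (SE 0.0602). Mitochondrially encoded transcripts rose in 7 of 9 cases (7 of 9 adjusted over the list alone, median 0.96, camera adjusted p = 2.13e-08). Their share of counts went from 0.90% ± 0.10 to 1.58% ± 0.06. Mitochondrial fatty acid oxidation genes rose in 12 of 24 cases and fell in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 0.0183, and adjusted p = 0.306 with an estimated correlation, and 0.0503 without Irgm1KO fenofibrate replicate 2). PPAR target genes were not called as a list (11 of 28 rose and 8 fell, 13 and 8 adjusted over the list alone, camera adjusted p = 0.216). Fabp5 was at 1.44 on the log2 scale (SE 0.125) and the acyl-CoA synthetase gene Acsl1 at -1.34 (SE 0.135). Proliferation genes rose in 32 of 40 cases and fell in 1 (33 and 1 adjusted over the list alone, camera adjusted p = 2.3e-14, and adjusted p = 0.201 with an estimated correlation). Kif23 went from 20.8 ± 0.961 to 53.8 ± 6.04 CPM, and glycolysis and hypoxia genes rose in 24 of 33 cases and fell in 1 (25 and 1 adjusted over the list alone, camera adjusted p = 2.13e-08, and adjusted p = 0.0911 with an estimated correlation). In total 3626 genes rose and 3427 fell.

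**Figure D3:**
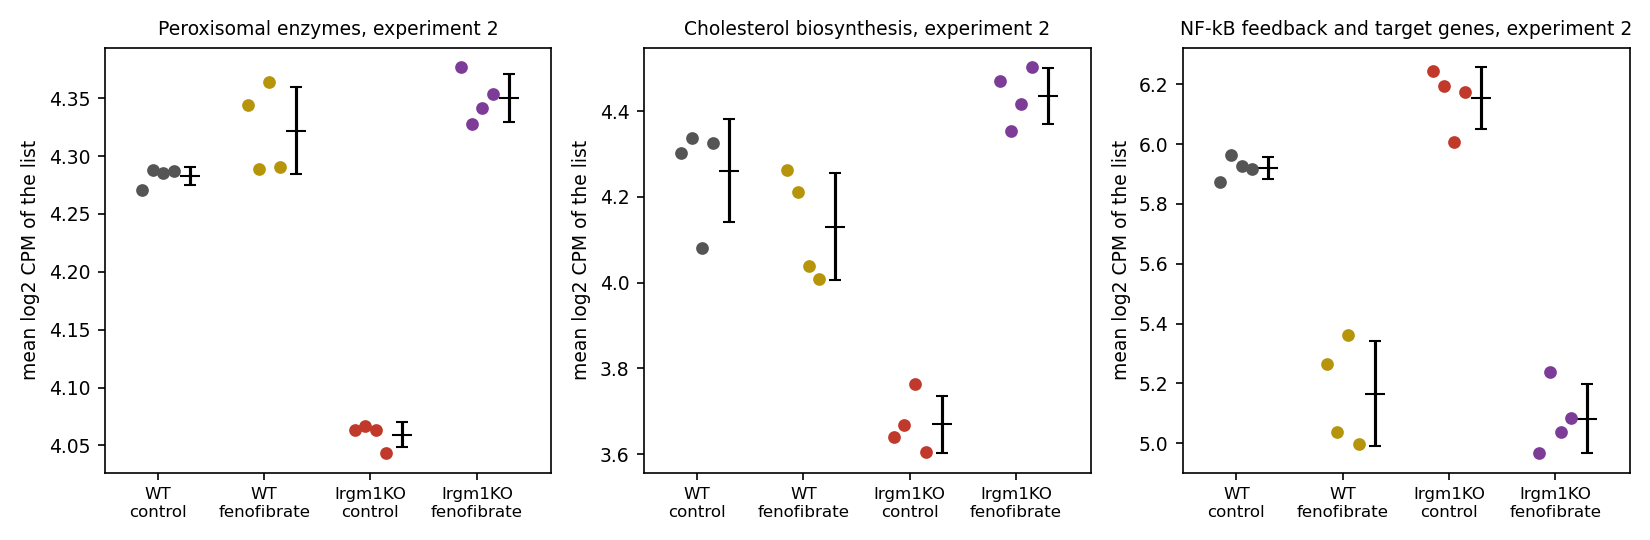
Mean log2 CPM (y axes, log2 scale) of peroxisomal enzymes, cholesterol biosynthesis genes and NF-kB genes in each library of the 4 groups of the second experiment (x axis). Points are libraries, and bars show the mean ± SD over 4 libraries. NF-kB values lie between 5.00 and 5.36 in WT fenofibrate and between 4.97 and 5.24 in Irgm1KO fenofibrate libraries. Cholesterol values lie between 3.61 and 3.76 in Irgm1KO control and between 4.36 and 4.50 in Irgm1KO fenofibrate libraries.

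The interaction of genotype and fenofibrate tested whether the drug's effect differed between Irgm1KO and WT cells. It did for 4565 genes, of which 2304 had a more positive and 2261 a more negative effect in Irgm1KO. Interferon-stimulated genes were lowered more in Irgm1KO in 50 of 56 cases and less in 1 (50 and 1 adjusted over the list alone, median difference -0.97, camera adjusted p = 2.13e-37, and adjusted p = 0.087 with an estimated correlation). For example, Isg15 differed by -1.63 (SE 0.24, adjusted p = 0.00015), while the Tnf effects differed by -0.16 (SE 0.119) and were not told apart (adjusted p = 0.34). Inflammatory cytokines and chemokines differed downward in 16 of 33 cases and upward in 2 (16 and 3 adjusted over the list alone). Their median difference was -0.54 (camera adjusted p = 0.00021, and adjusted p = 0.267 with an estimated correlation). Mitochondrially encoded transcripts differed upward in 8 of 9 cases (8 of 9 adjusted over the list alone, median 1.36, camera adjusted p = 3.53e-21). Cholesterol biosynthesis genes differed upward in 20 of 25 (23 adjusted over the list alone, median 0.76, camera adjusted p = 4.13e-18). Fatty acid synthesis genes differed upward in 12 of 23 with 2 downward (14 and 2 adjusted over the list alone, median 0.35, camera adjusted p = 1.33e-06). Peroxisomal enzymes differed upward in 16 of 39 with 2 downward (16 and 2 adjusted over the list alone, median 0.11, camera adjusted p = 0.00234). Fasn fell with the drug in WT, from 62.2 ± 4.61 to 43.3 ± 4.13 CPM, and rose in Irgm1KO (difference 1.38, SE 0.119). Proliferation genes differed upward in 26 of 40 cases and downward in 3 (27 and 4 adjusted over the list alone, camera adjusted p = 3.01e-13, and adjusted p = 0.297 with an estimated correlation). MHC class I genes differed downward in 17 of 21 (18 adjusted over the list alone, camera adjusted p = 6.85e-11, and adjusted p = 0.152 with an estimated correlation). NF-kB genes differed downward in 9 of 24 and upward in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00718, and adjusted p = 0.494 with an estimated correlation). ATF4 and unfolded protein response genes, with 13 upward and 16 downward among 33 (14 and 16 adjusted over the list alone), were not called (camera adjusted p = 0.298) except with same-numbered libraries of a genotype as a block (0.00651). Within that list Trib3 differed by -3.72 (SE 0.394) and Herpud1 by 1.04 (SE 0.0666). Macrophage markers differed upward in 5 of 10 cases and downward in 0 (5 and 0 adjusted over the list alone, median 0.26, camera adjusted p = 0.0447). That call was lost with an estimated correlation (0.669), the replicate number as a block (0.0627), RLE scaling and Xist as a covariate. It was also lost without WT control replicate 2 (0.0563) or 3 (0.0572), WT fenofibrate replicate 4 (0.0723), Irgm1KO control replicate 2 (0.073) or 3 (0.0828), or Irgm1KO fenofibrate replicate 1 (0.0577) or 4 (0.0731).

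Of 8245 genes changed by Irgm1 deficiency in this experiment, 4128 (50.1%) changed in the opposite direction with fenofibrate in Irgm1KO cells. Of 4219 risen genes 2070 fell and 321 rose further, and of 4026 fallen genes 2058 rose and 229 fell further. Independent lists would share 937 and 946. The correlation of the fold changes across genes was -0.61 and their covariance -0.293. Simulated unchanged groups around the same Irgm1KO control libraries gave -0.51 and -0.0263. They reversed 0 genes, an outcome fixed in advance because unchanged groups give almost no calls. The simulations drew all libraries independently, although same-numbered Irgm1KO control and fenofibrate libraries deviated together (r from 0.26 to 0.37). With those control libraries split 2 and 2, 2972 to 3236 genes reversed and the correlation lay between -0.52 and -0.44. Fewer genes could reverse in these splits, since 3475 to 3770 had risen and 3184 to 3594 had fallen against WT, compared with 4219 and 4026 unsplit. Between genotypes, the fenofibrate effects correlated across genes with r 0.36 and rho 0.36 over 15429 genes. Of 3142 genes called in both genotypes, 2606 (82.9%) went the same way, 1270 up and 1336 down. Independent lists would share 657 and 580, and 536 genes went opposite ways.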

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

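The counts of splits for the interaction that kept same-numbered libraries together, without and with a block, were chosen after the first result was seen; the other tests in this part were chosen before the data were examined.

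Fenofibrate had a different effect in Irgm1KO than in WT macrophages, by the interaction test itself, for 2304 genes with a more positive and 2261 with a more negative effect in Irgm1KO. The gene lists whose interaction held with an estimated correlation had median differences of 1.36 (mitochondrially encoded transcripts), 0.76 (cholesterol biosynthesis), 0.35 (fatty acid synthesis and desaturation) and 0.11 (peroxisomal enzymes). By the rule for named genes, which asks for a call and at least 5 CPM in the highest group, the largest upward differences on the log2 scale included those of Hpgd (3.48), Nxpe5 (3.35), Igfbp4 (2.82), Itga1 (2.80) and Fads2 (2.62). The largest downward differences by that rule were those of Hspa1b (-4.66), Cox6a2 (-4.46), Hspa1a (-4.18), Trib3 (-3.72), Slc7a5 (-3.23) and Cxcl11 (-3.15). These genes differ in what lies behind the number. Igfbp4, an insulin-like growth factor-binding protein gene, was low in Irgm1KO control cells at 6.74 ± 1.00 CPM (SD, n = 4) against 54.1 ± 5.50 in WT and rose with the drug to 37.5 ± 1.28. Cxcl11 was high in Irgm1KO control cells at 90.8 ± 15.9 CPM and fell with the drug to 4.15 ± 1.06. Cox6a2, a subunit gene of cytochrome c oxidase, went from 0.232 ± 0.0632 to 10.1 ± 5.37 CPM with the drug in WT and from 2.34 ± 0.29 to 4.52 ± 0.742 CPM in Irgm1KO.

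A gap test within groups of 4 libraries (Dixon's, at its 95% critical value) singled out 12 of 116 groups, where about 1 in 20 groups is singled out by chance. Irgm_IFNAR-KO replicate 3 had Ifnar1 at 53.1 CPM with the others at 108 to 114. Irgm1-KO replicate 3 had Isg15 at 1580 CPM with the others at 834 to 940, and Ifnb1 at 3.79 with the others at 1.4 to 1.73. Ifnb1 also stood apart in WT replicate 2 (0.217 CPM) and Irgm_IFNAR-KO replicate 4 (0.625 CPM), at a level of few counts. The libraries where Ifnb1 stood apart are the 3 of the first experiment farthest out within their groups. The flagged Isg15 value and the flagged interferon-stimulated list value below come from libraries of this set. Whether the spread within groups underlies these flags was not tested. Tnf was at 17.1 CPM in WT fenofibrate replicate 4. The share of the unnamed gene ENSMUSG00000119584 stood apart in WT fenofibrate replicate 2 (6.24%), Irgm1KO fenofibrate replicate 1 (8.13%) and WT replicate 3 (1.59%). Mean log2 CPM of a list stood apart in Irgm_IFNAR-KO replicate 4 for interferon-stimulated genes (5.59), in Irgm1KO control replicate 4 for peroxisomal enzymes (4.04) and in WT control replicate 3 for cholesterol biosynthesis (4.08).

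In the 4 comparisons between genotypes the real split alone, 1 of 35, gave as many called genes. This argues against chance assignment of libraries to groups without excluding it, since 1 of 35 is the smallest share possible. The other splits mix genotypes and carry the tested difference in their residual spread, which can lower their counts. The real and highest other counts were 5660 and 2648 for Irgm1-KO against WT, 5998 and 0 for Irgm_IFNAR-KO against Irgm1-KO, 1702 and 0 for Irgm_IFNAR-KO against WT, 8245 and 0 for Irgm1KO against WT controls, and, over 35 splits that ignore pairing, 5407 and 2 for fenofibrate in WT and 7053 and 898 for fenofibrate in Irgm1KO. The 2648 came from exchanging WT replicate 1 with Irgm1-KO replicate 3. In the fenofibrate comparisons, where numbers pair the libraries, 8 splits part every pair, which is too few for a share under 0.05. The real counts were 5407 and 7053, and the 7 other such splits, which exchange control and fenofibrate within 1 or more pairs, called 0 genes at most. For the interaction, 2 of 100 labelings, the real one included, called at least the real 4565 genes, and the other called 4574. That labeling, and a further one that called 3876, kept the control labels and mixed genotypes among the fenofibrate libraries, so both take in the genotype difference of the controls. With same-numbered libraries kept together, 1 of 35 splits, the real one, reached 4565 and the highest other called 0. These counts decide nothing about chance in the interaction. Splits that mix genotypes carry the genotype difference, which is not the effect tested there, in their residual spread. With same-numbered libraries of a genotype also taken as a block, which removes that difference, 1 of 35 splits, the real one, reached 5915 genes. The highest other called 0. This argues against chance for the interaction without excluding it, since 1 of 35 is the smallest share possible. The block was also chosen after the first result was seen. Splits that mix genotypes still carry the tested difference in drug effect in their residual spread.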

How the results depend on the processing

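The block within genotype, the fit without the unnamed gene and the fit without 3 libraries were chosen after the data were seen, and all other alternatives before. No direction reversed among the called results. Of 137, 142, 103, 143, 125, 135 and 124 named genes called in the 7 comparisons, in the order of the report, 134, 137, 87, 140, 122, 126 and 119 kept their call in every alternative. Over 214 list results, 1508 alternative values stayed on the same side of the threshold, 83 gained a call and 90 lost one, and estimated correlation accounts for 71 of the losses and fry, which asks another question than camera, for 54 of the gains. Lists called with a preset correlation numbered 15, 13, 11, 13, 13, 15 and 13 of 23, and with an estimated one 5, 6, 3, 0, 0, 8 and 4. Xist as a covariate raised the genes that rose to 4252 in Irgm1-KO against WT and 4640 in Irgm_IFNAR-KO against Irgm1-KO, and gave 2126 rises and 2132 falls in Irgm_IFNAR-KO against WT. The axis that Xist follows is treated among the other observations. Leaving out 1 library gave 337 to 542 rises in Irgm_IFNAR-KO against WT, below 552 in part because fewer libraries test less. The values 337, 360 and 361 came without Irgm_IFNAR-KO replicates 3, 2 and 1, and 367 without WT replicate 3. The correlation of fenofibrate effects between genotypes was 0.43 over genes of at least 5 CPM against 0.36, and the cause was not tested. Reversed genes numbered 3150 to 5951 in Irgm_IFNAR-KO, against 4503, and 2972 to 4525 with fenofibrate, against 4128.

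The planned replicate block, with numbers that pair libraries within a genotype only, gave 2599 rises and 2639 falls in Irgm1-KO against WT and 4170 and 4005 in Irgm1KO against WT controls. In the latter, replicate block values of LXR targets (0.0367), NRF2 genes (0.0367) and markers of macrophages (0.037), neutrophils (0.029), fibroblasts (0.037) and osteoclasts (0.0466) passed the threshold, and for the interaction that of macrophage markers (0.0627) no longer did. Same-numbered libraries correlated with r from -0.29 to 0.03 between genotypes of the second experiment and from -0.48 to 0.52 in the first, where a library correlated best with its own number in 1 of 4 cases per pair of groups. The block within genotype gave 3505 rises and 3241 falls for fenofibrate in WT, 4168 and 4007 in Irgm1KO and 2972 and 2943 for the interaction, and among lists it changed the calls of ATF4 genes with fenofibrate in Irgm1KO (0.0553), osteoclast markers in WT (0.0109) and, for the interaction, LXR targets (0.0363), NRF2 genes (0.0481) and ATF4 genes (0.00651). Of named genes 18 gained and 0 lost their call with it, and no other list call changed. DESeq2 called 3269 rises and 3090 falls in Irgm1-KO against WT. Small changes were recovered least in simulations of the first experiment, where edgeR found at most 41.8% of 1.5-fold changes and DESeq2 58.2% to 68.7%. That experiment had both fewer counts per library and a larger biological coefficient of variation (0.172 against 0.12), and which of these limits the recovery was not tested.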

Other observations

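The tests of transcript length, of the unnamed gene, of Xist, of the sex of the animals, of other heat-shock genes, of the receptor and of the split WT libraries were chosen after the result was seen; those of depth, immediate-early genes and flanking DNA were chosen before.

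With fenofibrate, lysosomal genes were called as a list in both genotypes and antioxidant genes in WT. These calls were lost with an estimated correlation (adjusted p = 0.497, 0.395 and 0.404). In WT cells 23 of 46 lysosomal genes rose and 6 fell (23 and 7 adjusted over the list alone, camera adjusted p = 0.00408, and adjusted p = 0.497 with an estimated correlation). Among them was the iduronidase gene Idua (log2 fold change 0.53, SE 0.0673), while the protease gene Ctsc fell (-0.90, SE 0.116). In Irgm1KO cells 24 rose and 7 fell (26 and 7 adjusted over the list alone, camera adjusted p = 0.000625, and adjusted p = 0.395 with an estimated correlation). The saposin precursor gene Psap rose by 0.62 (SE 0.0617). NRF2 and oxidative stress genes rose in 16 of 29 cases in WT and fell in 3 (16 and 6 adjusted over the list alone, camera adjusted p = 0.00114, and adjusted p = 0.404 with an estimated correlation). In Irgm1KO that list was not called (9 of 29 rose and 3 fell, 7 and 2 adjusted over the list alone, camera adjusted p = 0.295). In WT the glutathione transferase gene Gstm1 rose by 1.33 (SE 0.185), and Nfe2l2, which encodes NRF2 itself, fell by 0.54 (SE 0.0641). The autophagy and mitophagy list fell in Irgm1KO against WT controls (15 of 39 fell and 7 rose, 15 and 7 adjusted over the list alone, camera adjusted p = 0.0282, and adjusted p = 0.439 with an estimated correlation). The mitophagy kinase gene Pink1 fell by 1.32 (SE 0.0894) and Ulk1, which starts autophagy, by 0.76 (SE 0.0462). In Irgm1-KO against WT of the first experiment that list was not called (7 of 39 rose and 8 fell, camera adjusted p = 0.949). Pink1 fell there from 52.5 ± 3.87 to 16.5 ± 0.553 CPM and the cargo receptor gene Sqstm1 rose from 381.5 ± 15.4 to 1214 ± 71.9 CPM (SD, n = 4).

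Among markers of other cell types, dendritic cell markers fell with fenofibrate in WT (2 of 4 fell and 0 rose, 2 and 0 adjusted over the list alone, camera adjusted p = 0.0145, and adjusted p = 0.126 with an estimated correlation). Endothelial markers fell in Irgm_IFNAR-KO against WT (2 of 3 fell, 2 adjusted over the list alone, camera adjusted p = 0.00772, and adjusted p = 0.065 with an estimated correlation). Osteoclast markers with fenofibrate in WT, with 2 rises among 5 (3 adjusted over the list alone), were not called (camera adjusted p = 0.229), but were with same-numbered libraries of a genotype as a block (0.0109) and with fry (0.0483). T cell markers (2 rises and 1 fall among 3, camera adjusted p = 0.726) were not called in Irgm1KO against WT controls. Lists of B cell, NK cell, mast cell and basophil, eosinophil, erythroid and megakaryocyte markers had fewer than 3 measured members and were not tested.

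Libraries of the first experiment spread within their groups along 1 axis that held 53.8% of the within-group variance. No relation was found with depth (r = 0.18, permutation p = 0.581, rho 0.33, over 12 libraries centred by group) or with the share of the unnamed gene (r = -0.14, permutation p = 0.653, rho -0.22). Across genes, weight on the axis correlated with transcript length (Spearman's rho -0.40, genes not being independent), with median lengths of 659 and 2304.5 bases for the 500 genes at either end, and log2 Xist followed it (r = -0.95, permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 3e-05 over 3 relations, rho -0.93, and r = -0.90 without the 2 farthest libraries). The axis may therefore be one of transcript length, such as differing RNA quality or library preparation. Xist, a long transcript present in all 12 libraries at 50.6 to 231 CPM, may mark it. Xist was read from the same counts that define the axis, so its permutation p is not that of an independent measure. How many other genes follow the axis as closely was not examined, so Xist is not shown to be a special marker. Male animals in some libraries and female animals in others are argued against as the source of the axis. The lowest Xist, 50.6 CPM, lies far above the 0 to 1.78 CPM of the 6 libraries of the second experiment with Y-linked expression, and the 10 without it had 50.2 to 143. Libraries pooled from both sexes are not favoured either, since no Y-linked gene is listed in the first table, where every listed gene reaches 10 counts in some library. A gene that is not listed has no value, so this alone does not exclude them.

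Heat-shock genes were raised in Irgm1-deficient cells in both experiments. The pattern was not limited to the locus of Hspa1a and Hspa1b: of 21 other heat-shock genes 19 rose in each experiment, with medians of 0.83 (bootstrap interval 0.59 to 1.00) and 0.84 (0.69 to 1.03). Receptor signalling as the whole cause is argued against by Hspa1a, which stayed 3.69 higher on the log2 scale in Irgm_IFNAR-KO than in WT. Of the 21 others, 13 were higher there than in WT and 0 lower, with a median of 0.49 (0.39 to 0.60). Part of the rise was lost, with 12 of the 21 falling against Irgm1-KO, and 17 falling with fenofibrate in Irgm1KO. Stress at harvest cannot be told apart from an effect of genotype, since immediate-early genes had medians of -0.15 (-0.87 to 0.52) and 0.32 (0.05 to 0.78), with 6 rises and 7 falls in the first experiment and 9 rises and 1 fall in the second. A lasting proteotoxic stress of Irgm1-deficient cells is a hypothesis that these counts do not test.

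Against WT, 662 genes changed the same way in Irgm1-KO and Irgm_IFNAR-KO and 589 changed opposite ways, with the WT libraries in both comparisons. With those split 2 and 2, 297 of the 662 were called the same way in each of the 6 splits, which test with fewer libraries. DNA carried along with the Irgm1 mutation is a candidate source of such changes. Of 79 tested genes within 5 Mb of Irgm1 in the annotation, 3 were among the shared changes, against 658 of 13871 other genes (odds ratio 0.793, 95% interval 0.159 to 2.42, Fisher's exact p = 1, two-sided), an interval too wide to exclude an enrichment. The 3 are Timd4 (5.66 and 4.95 on the log2 scale in Irgm1-KO and Irgm_IFNAR-KO), Sqstm1 (1.67 and 0.25) and Havcr2 (-0.38 and -1.12), the last chosen after its values were seen. They were called the same way in 6, 1 and 4 of the 6 splits. Timd4 and Havcr2 are known neighbours of 1 gene family, so a local sequence difference may underlie them, and this stays open. No excess of called genes within 5 Mb of a targeted locus was detected, with odds ratios of 0.853 (p = 0.566), 0.929 (p = 1) and 0.833 (p = 0.44) for Irgm1 in Irgm1-KO against WT, Irgm_IFNAR-KO against WT and the second experiment, and 1.2 (p = 0.505) and 0.849 (p = 0.841) for Ifnar1 in Irgm_IFNAR-KO against Irgm1-KO and WT (Fisher's exact test, two-sided).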
